A study of Mus musculus with 6 samples.

How the data were processed

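RNA sequencing was carried out on dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, taken between thoracic level 8 and lumbar level 2. The 6 libraries came from 6 wild-type mice, 3 sham-operated and 3 with renal ischemia-reperfusion (I/R), with 1 library per mouse. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a stranded Illumina mRNA kit. The submitters' processing notes name fastp, HISAT2, StringTie and the mouse assembly GRCm39, with no role, order or version. The program that made the counts, its strand setting and the annotation release are not given in the sources used here.

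The authors deposited 1 table of 57180 Ensembl genes, with an estimated read count per gene and library that was not scaled to library size. Between 10.7% and 11.5% of the values in a library were not whole numbers, so the deposited values were taken to be expected counts and were rounded to whole numbers before testing. The design fixed before the data were examined had assumed whole counts, and the test was kept. The authors' 2 columns of group means and the gene length column were not used in any test of genes or gene lists. Gene symbols were taken from the deposited table. The reference genome at hand was of another assembly than GRCm39, so no coordinates are given.

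Library totals ran from 19092650 to 22010227 expected counts. A count of 3 in a library, the most that a count of 0 allows, corresponded to 0.137 to 0.154 CPM, the count scaled to library size. This limit and counting intervals cover counting error only, because reads without molecular identifiers are not independent molecules. No pair of libraries from 1 group agreed within sampling noise, with a chi-square per degree of freedom of 4.15 to 30.9 over genes, so all 6 libraries were counted as separate replicates.

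Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the package's filter on low counts (16346 genes kept) and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Unless another fit is named, calls rest on all 6 libraries and on the genes kept by this filter. Fold changes are I/R over sham on the log2 scale, standard errors (SE) were derived from the log2 fold change and the F statistic, and levels are CPM with TMM-scaled library sizes, as mean ± SD. The biological coefficient of variation was 13.2%. Counts with known changes were simulated over 16132 genes, with the changed genes drawn among those with a mean of at least 1 CPM. The test recovered 22.4% of genes changed 1.5-fold, 70.2% of those changed 2-fold and 98.5% of those changed 4-fold. Of its 133 calls, 6 (4.51%) were of unchanged genes. Recovery of genes with a lower mean was not measured. A change under about 2-fold could therefore often be missed.

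Before the data were examined, 35 gene lists were fixed, of programs, cell types and RNA quality. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, two-sided, with adjustment over the lists. The test was repeated with an estimated correlation and with fry. On the simulated counts the 1 shifted list was called, and 0 of the 34 others were. Those counts were drawn independently for each gene, so they give no measure of false list calls where genes are correlated.

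Genes named in the text followed a rule fixed before the data were examined. It took the 12 largest and 12 smallest log2 fold changes among called genes with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted genes. It always took Calca, Tac1, Trpv1, Atf3 and Il4ra. It took up to 4 members of smallest p from each list that was called or had a called member, and up to 2 from other lists. Csf1, Sox11, C3, Adam8, Rbp4, Lox, Loxl2, Col1a1, Col3a1, Slc22a6, Slc13a4, Slc47a1, Pcolce, Cdh1, Lipn, Gm5152, Gm3883, Gm21451 and Tnfrsf8 fall outside it and were chosen after their values were seen. Some genes that the rule takes are not reported here.

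The alternatives were RLE and upper-quartile normalization, DESeq2 1.42.0, limma-voom, robust dispersion, no filter on low counts, a CPM of at least 1 in 3 libraries, the replicate number as a block, and leaving out each library in turn. A fit with each library's skeletal muscle level as a covariate, and one of sham 2 alone against I/R, were added after seeing the data. Enrichment of the authors' Gene Ontology terms was also added after seeing the data, as a one-sided hypergeometric test of biological process terms of 10 to 500 genes among tested genes with such a term, and was repeated without predicted and unnamed genes. For explanations tested on a gene list, the list's median was given a 95% interval from 10000 bootstrap draws of its genes. Such an interval covers the spread among the genes of the list and not the variation between mice. The interval was added after the medians had been seen. An explanation was set aside only where the whole interval passed the bound that speaks against it.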

Results

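The transcriptome of mouse dorsal root ganglia was measured 24 h after kidney surgery. In I/R mice the left renal pedicle, which carries the vessels and nerves of the kidney, had been clamped for 28 min and then released, and the right kidney had been removed. Per the labels, sham mice had the same procedures without the clamp, but removal of the right kidney is not stated for them separately, and if it was not done each difference between the groups would include that operation. The title of the series places the experiment in a study of pain-sensing nerves and macrophages in the injured kidney, and the comparison asks how sensory ganglia changed after renal I/R. Each group held 3 mice. Library totals were 20390927, 20124324 and 19092650 expected counts in sham 1 to 3 and 20234079, 20931650 and 22010227 in I/R 1 to 3.

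Among named genes with a mean of at least 1 CPM, several known from injured sensory neurons were among the largest increases in I/R ganglia. Sprr1a, a small proline-rich protein induced in sensory neurons whose axons are damaged, rose from 0.467 ± 0.12 to 83.6 ± 15.1 CPM (SD, n = 3 per group), a 176-fold change. Atf3, a transcription factor induced by axon injury, rose from 9.17 ± 0.788 to 126 ± 15.5 CPM. Ptgds, the lipocalin-type prostaglandin D synthase that meningeal cells make in large amounts, fell from 128 ± 21.1 to 17.4 ± 4.2 CPM. Transcripts of the nociceptor markers Calca, Tac1 and Trpv1 did not pass the test. In all, 188 of 16346 tested genes were called with edgeR's quasi-likelihood test, 118 higher and 70 lower in I/R, and 113 of them changed at least 2-fold. The 3 I/R values lay all above or all below the 3 sham values for 17.1% of tested genes. Random grouping gives 10% on average. Genes vary together across libraries and the share was not computed for other groupings, so an excess was not tested. The count fell to 93 without sham 1, to 87 without I/R 2 and to 98 without I/R 3, and was 32 with sham 2 alone against I/R, an alternative added after seeing the data.

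**Figure D1:**
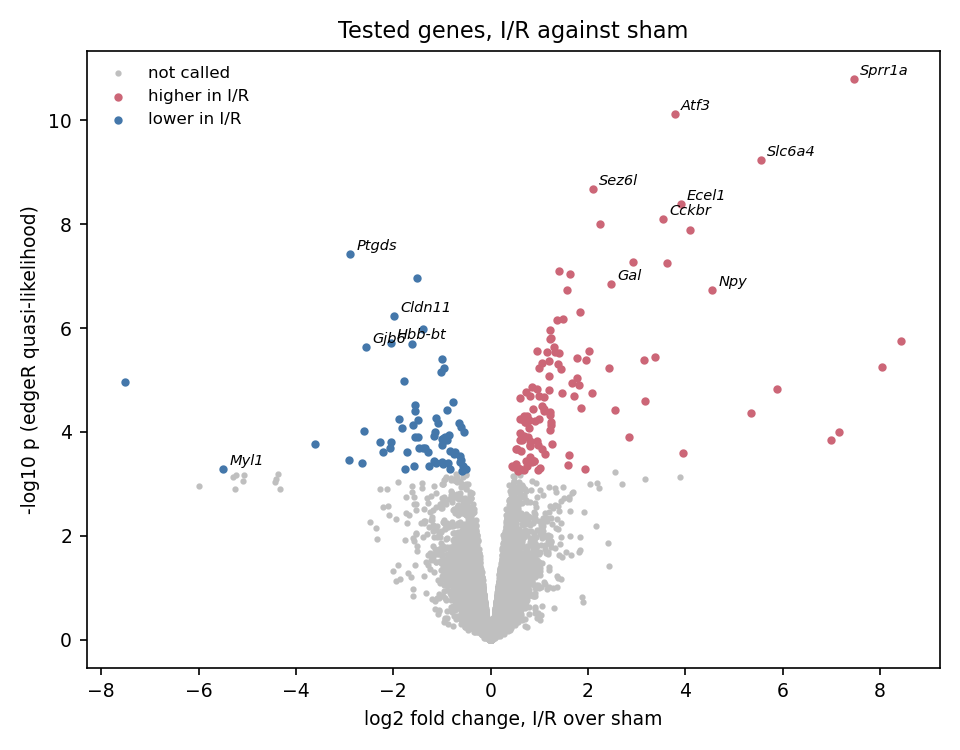
Each point is 1 of the 16346 tested genes, with the log2 fold change of I/R over sham on the x axis and the unadjusted p of edgeR's test on the y axis as its negative log10. Colored points are the 118 genes called higher and the 70 called lower, with Sprr1a (log2 fold change 7.46) and Atf3 (3.79) at the top right and Ptgds (-2.89) at the top left.

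Among the 12 largest increases under the naming rule, several genes encode receptors, transporters or peptides. Slc6a4, the serotonin transporter, rose from 0.200 ± 0.0479 to 9.70 ± 0.980 CPM (log2 fold change 5.55 ± 0.24 SE, adjusted p = 3.2e-06 in edgeR's test). Npy, which encodes neuropeptide Y, rose by 4.55 ± 0.36, and Gpr151, an orphan receptor of sensory and habenular neurons, by 4.09 ± 0.24. Ecel1, a neuronal peptidase, rose by 3.90 ± 0.20 and Fgf3, a fibroblast growth factor, by 3.62 ± 0.25. Cckbr, a cholecystokinin receptor, rose from 0.603 ± 0.0976 to 7.10 ± 0.173 CPM, by 3.55 ± 0.20 on the log2 scale. Kcnk16, a background potassium channel, rose by 3.37 ± 0.36, Wfdc3 by 3.14 ± 0.35, and Etnppl, an enzyme of phosphoethanolamine breakdown, by 2.93 ± 0.20. Sprr1a and Atf3 had adjusted p of 2.6e-07 and 6.1e-07. The value for Kcnk16 was 3.95 without sham 3.

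**Figure D2:**
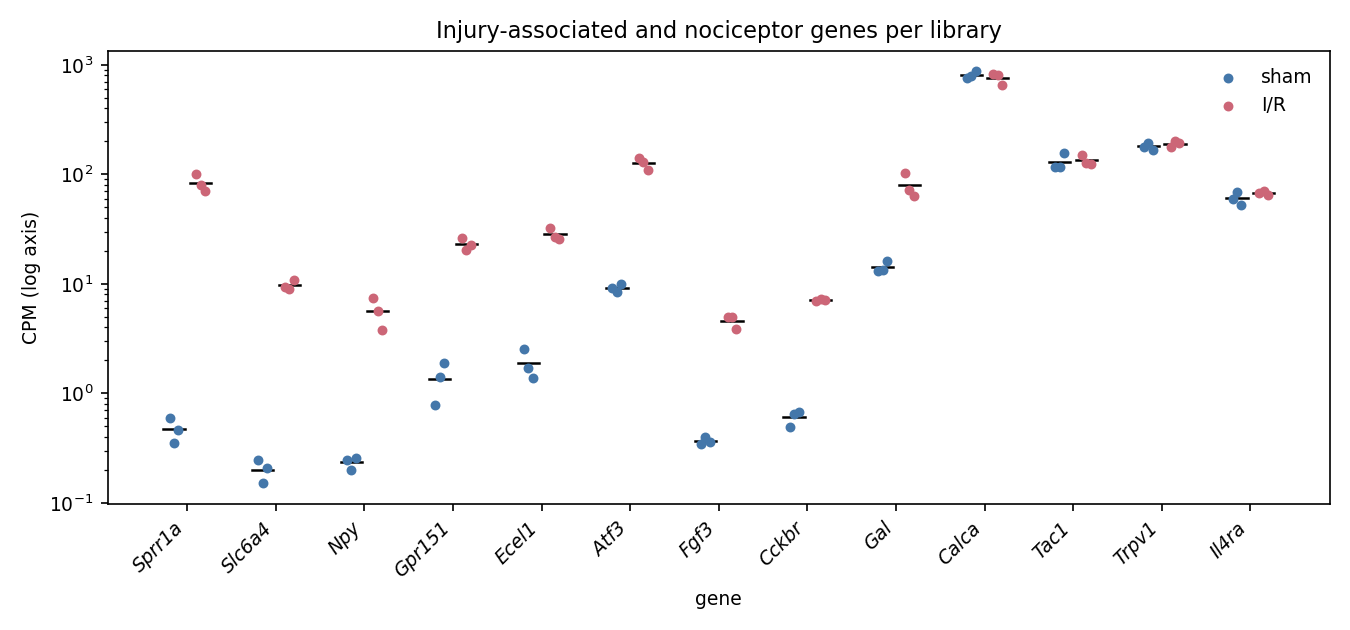
CPM of 13 genes on a log axis, with 1 point per library and a bar at the group mean of 3 sham or 3 I/R libraries. The points of Sprr1a, Slc6a4, Npy, Gpr151, Ecel1, Atf3, Fgf3, Cckbr and Gal are separated between the groups, and those of Calca, Tac1, Trpv1 and Il4ra overlap.

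The nerve injury and regeneration list rose as a group. Of its 19 measured members, 15 rose and none fell among calls over all genes, 18 rose when adjusted over the list alone, and the median log2 fold change was 1.46 (camera adjusted p = 5.9e-36). With an estimated correlation the list had adjusted p = 0.0702. Besides Sprr1a, Atf3, Ecel1 and Cckbr, the called members include Csf1, the growth factor of macrophages and microglia, which rose from 22.5 ± 2.05 to 60.0 ± 1.2 CPM, and Sox11, a transcription factor of growing neurons, which rose from 9.05 ± 0.581 to 28.2 ± 2.61 CPM. Csf1 and Sox11 were chosen after their values were seen. Against sham 2 alone, a fit that rests on 1 sham library, the list's median log2 fold change was 1.57. All 15 called members lay above 0 there. This was all but fixed in advance, because each of their I/R values lay above each of their sham values.

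Peptide genes also rose, in part. The neuropeptide list was called higher (camera adjusted p = 0.0023), but had adjusted p = 0.54 with an estimated correlation and 0.064 by fry. Of 13 measured members, 5 rose over all genes, and 5 rose and 2 fell when adjusted over the list alone, with a median log2 fold change of 0.10. Gal, which encodes galanin, rose from 14.2 ± 1.79 to 79.5 ± 21.4 CPM (2.48 ± 0.19), and Nts, which encodes neurotensin, rose from 6.90 ± 1.76 to 18.9 ± 3.05 CPM (1.46 ± 0.19). Crh, the corticotropin-releasing hormone gene, had 2 counts over the sham libraries and 100 over the I/R libraries, a ratio of 47.6 with a 95% counting interval of 12.8 to 399. Adcyap1, which encodes the peptide PACAP, rose by 0.61 ± 0.09. All 5, Npy included, are also on the injury list, so the lists are not independent. Crh lost its call without sham 1 (adjusted p = 0.0551), and its fitted log2 fold change was 8.05 without sham 2, the one sham library with counts, and is then no bound. Adcyap1 lost its call without sham 1, sham 2 or I/R 2 (adjusted p 0.0515 to 0.0992).

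Most markers of nociceptor identity did not pass the test. Calca, which encodes the peptide CGRP, stood at 807 ± 57.3 CPM in sham and 763 ± 91.1 CPM in I/R (log2 fold change -0.08 ± 0.11, adjusted p = 0.84). Tac1, the substance P gene, differed by 0.05 ± 0.14 (adjusted p = 0.93) and Trpv1, the capsaicin receptor, by 0.09 ± 0.10 (adjusted p = 0.82). Of the 12 peptidergic nociceptor genes, 1 rose, Adcyap1, and the list was not called (camera adjusted p = 0.97), with 1 higher and 1 lower when adjusted over the list alone. The 14 non-peptidergic and pruriceptive genes were lower as a group (median -0.25, camera adjusted p = 0.018), with adjusted p = 0.39 with an estimated correlation and 0.088 by fry. With the filter on low counts, none of the 14 was called over all genes by edgeR, DESeq2 or limma-voom, or over the list alone in edgeR's test. Of the 14, 7 had an unadjusted p under 0.05 in edgeR's test, and their lowest values were -0.78 for Mrgprb5 and -0.76 for Sst. Without the filter, edgeR called Sst (adjusted p = 0.042). That list lost its call without I/R 1 (adjusted p = 0.18), with the muscle level as a covariate (0.0816) and against sham 2 alone (0.0651). Of 12 large-diameter neuron genes none was called by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05 (median 0.02, camera adjusted p = 0.96), with Ntrk3 at 0.16 and Esrrg at 0.15.

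Ion channels and activity genes showed single changes. Of 21 ion channel genes of pain, Cacna2d1, a calcium channel subunit bound by gabapentin, rose from 131 ± 17.2 to 225 ± 26.4 CPM (0.79 ± 0.12). The sodium channel gene Scn9a had a log2 fold change of 0.31 (adjusted p = 0.36). The list was not called (camera adjusted p = 0.44), and 2 members were higher when adjusted over the list alone. Cacna2d1 lost its call without sham 1, I/R 2 or I/R 3 (adjusted p 0.0514 to 0.102). Of 18 immediate early genes, Fosl2 rose by 0.86 ± 0.11 and Dusp1 by 0.77 ± 0.12, and the list was not called (camera adjusted p = 0.14), with 2 higher and 1 lower when adjusted over the list alone. The list was called higher without sham 2 (adjusted p = 0.0185) or I/R 3 (0.0178). Dusp1 lost its call without sham 1 or I/R 2 (adjusted p 0.0719 and 0.0634).

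**Figure D3:**
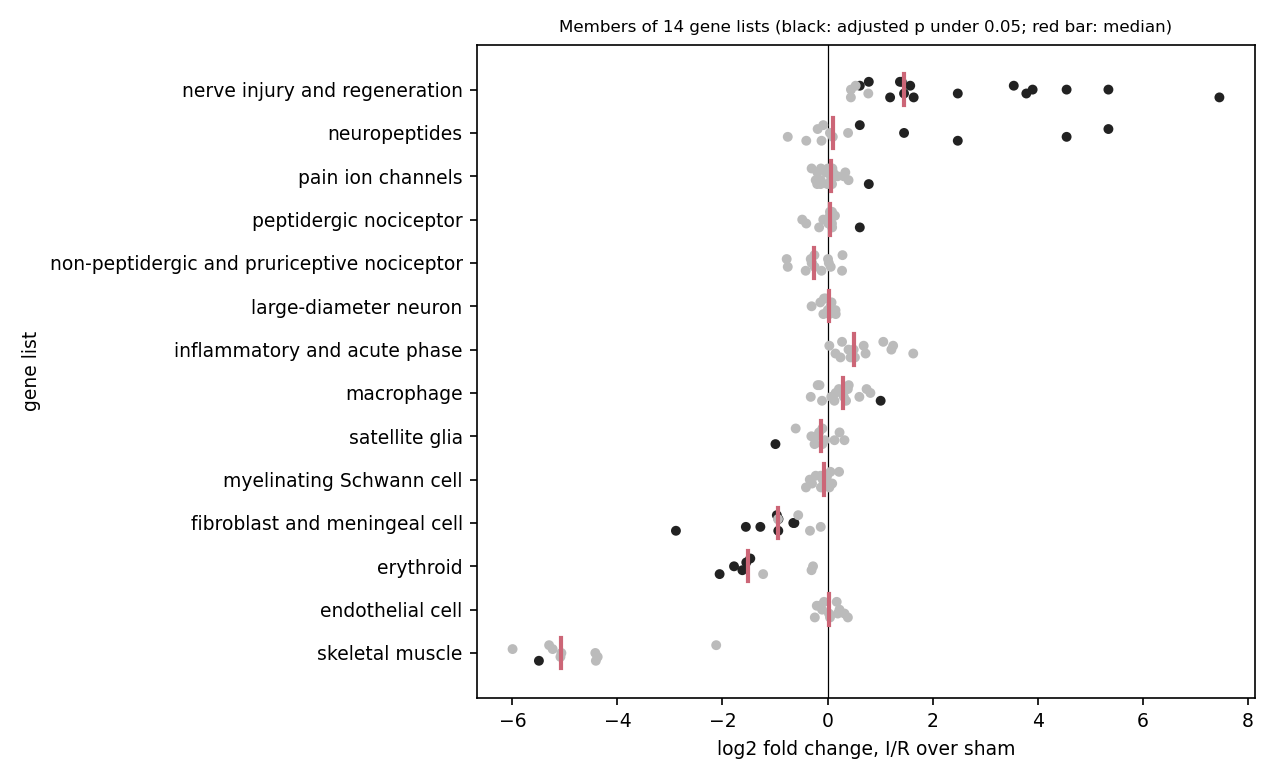
Log2 fold change of I/R over sham for the measured members of 14 gene lists, with 1 point per gene, black where edgeR's adjusted p was under 0.05, and a red bar at the list median. The nerve injury list has its median at 1.46, the fibroblast and meningeal list at -0.94, the erythroid list at -1.51 and the skeletal muscle list at -5.08.

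Connective tissue and meningeal genes fell. Of the 12 members of the fibroblast and meningeal list, 8 fell over all genes and 10 when adjusted over the list alone, and the median log2 fold change was -0.94 (camera adjusted p = 1.5e-13). With an estimated correlation the list had adjusted p = 0.15. Ptgds fell by 2.89 ± 0.19 on the log2 scale (adjusted p = 7.0e-05), and Slc6a13, a GABA and taurine transporter, fell by 1.55 ± 0.21. The proteoglycan genes Lum and Dcn fell, with log2 fold changes of -0.93 ± 0.15 and -0.65 ± 0.10. Col1a1 and Col3a1, fibrillar collagen genes chosen after their values were seen, fell, with values of -0.97 and -0.94. Lum lost its call without sham 1, I/R 2 or I/R 3 (adjusted p 0.0599 to 0.109), Col1a1 without sham 1, I/R 1 or I/R 3 (adjusted p 0.0503 to 0.116), Dcn without I/R 2 (adjusted p = 0.0842) and Col3a1 without I/R 3 (adjusted p = 0.132). The skeletal muscle genes, summed, stood at 473, 16.2 and 246 CPM in sham 1 to 3 and at 6.67, 12.3 and 9.49 CPM in I/R 1 to 3.

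Other genes among the 12 largest decreases under the naming rule included Cldn11, Gjb6 and Aldh1a2. Cldn11, a tight junction gene of the arachnoid barrier and of myelin, fell from 11.1 ± 0.777 to 2.82 ± 0.616 CPM (log2 fold change -1.97 ± 0.17, adjusted p = 0.00051 in edgeR's test). Gjb6, a connexin gene, fell by 2.55 ± 0.26, and Prg4, which encodes lubricin, fell by 1.82 ± 0.28. Aldh1a2, which makes retinoic acid, Stra6, a retinol uptake receptor, and Crabp1, a retinoic acid binding protein, fell, with log2 fold changes of -2.06 ± 0.36, -1.87 ± 0.28 and -1.71 ± 0.31. Mcpt4, a mast cell protease, fell by 2.04 ± 0.34. Aldh1a2 (adjusted p 0.0599 to 0.0909) and Crabp1 (0.0556 to 0.12) lost their calls without sham 1, sham 2, sham 3, I/R 2 or I/R 3, Mcpt4 without sham 2, sham 3, I/R 2 or I/R 3 (0.0560 to 0.132), and Stra6 (0.0889) and Prg4 (0.0908) without I/R 3.

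Skeletal muscle transcripts were abundant in sham 1 and sham 3. The list was lower in I/R (median log2 fold change -5.08, camera adjusted p = 4.5e-08), with adjusted p = 0.39 with an estimated correlation and 0.17 by fry. With its own level as a covariate the list turned upward (camera adjusted p = 0.962), an outcome that this covariate all but fixes. Of 10 measured members, Myl1, a myosin light chain, fell over all genes and 10 fell when adjusted over the list alone, while DESeq2 called 10 over all genes and limma-voom none. Myl1 stood at 15.1, 0.700 and 10.8 CPM in sham 1 to 3, and at 0, 0.339 and 0.228 CPM in I/R 1 to 3, and the muscle glycogen phosphorylase Pygm, outside the list, fell by 2.65 ± 0.51. Both lost their calls without sham 1, sham 3, I/R 1, I/R 2 or I/R 3 (adjusted p 0.119 to 0.254 for Myl1 and 0.0989 to 0.226 for Pygm), and in limma-voom (0.46 and 0.18). The log2 fold change was -2.01 for Pygm and -4.89 for Myl1 without sham 1, and for Myl1 -6.18 without I/R 2. Mobp, an oligodendrocyte gene on the spinal cord list, followed the same libraries, with 18.7, 3.20 and 12.7 CPM in sham 1 to 3 and 1.68, 3.53 and 2.83 CPM in I/R 1 to 3, and was called without sham 2 (adjusted p = 0.0014).

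**Figure D4:**
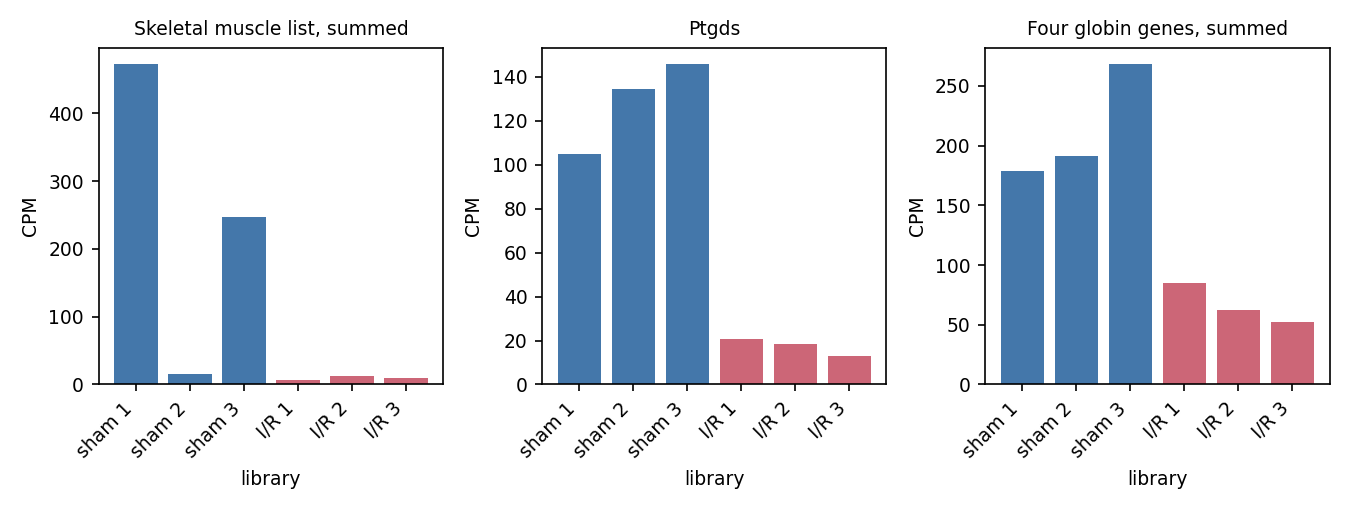
Summed CPM of the skeletal muscle list, CPM of Ptgds, and summed CPM of 4 globin genes, with 1 bar per library. The muscle genes reach 473 and 246 CPM in sham 1 and sham 3 and at most 16.2 CPM elsewhere, whereas Ptgds and the globin genes are lower in each I/R library than in each sham library.

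Red cell transcripts fell. Of 8 erythroid genes, 5 fell over all genes and 7 when adjusted over the list alone, with a median log2 fold change of -1.51 (camera adjusted p = 8.9e-11). With an estimated correlation the list had adjusted p = 0.27. The beta globin genes Hbb-bt and Hbb-bs fell, with log2 fold changes of -2.05 ± 0.21 and -1.55 ± 0.22, and so did the alpha globin genes Hba-a2 and Hba-a1, with -1.78 ± 0.22 and -1.62 ± 0.16. Because each pair is nearly identical in sequence, the split within a pair is uncertain. Summed, the 4 genes stood at 179, 191 and 268 CPM in sham 1 to 3 and at 85.3, 62.5 and 52.0 CPM in I/R 1 to 3. Hbb-bs lost its call without I/R 2 (adjusted p = 0.0701).

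Macrophage and inflammatory genes leaned higher as groups, with few called singly. Of 17 macrophage genes, 13 lay above 0 and 4 below, and all 14 inflammatory genes lay above 0. The macrophage list had a median log2 fold change of 0.30 (camera adjusted p = 0.0034), with adjusted p = 0.19 with an estimated correlation. Of its 17 measured members, Cd163, a scavenger receptor for hemoglobin, rose from 3.04 ± 0.427 to 6.14 ± 1.26 CPM, and 2 rose when adjusted over the list alone. Mertk stood 0.61 higher (adjusted p = 0.080, and 0.041 without I/R 1). Cd163 lost its call whichever of the 6 libraries was left out (adjusted p 0.0755 to 0.159). The inflammatory and acute phase list had a median of 0.51 (camera adjusted p = 4.4e-08), with adjusted p = 0.0702 with an estimated correlation. With the filter on low counts, none of its 14 measured members was called over all genes in edgeR's test or limma-voom and 2 were in DESeq2. Without the filter, members that edgeR called included Il1r1, Lrg1, Serpina3n and Lcn2 (adjusted p 0.0075 to 0.0311). That fit also called Mobp, whose groups overlapped (adjusted p = 4.1e-06), so its added calls are weak. In edgeR's main fit 10 members had an unadjusted p under 0.05, and 10 rose when adjusted over the list alone. Lcn2 and Lrg1, acute phase genes, stood 1.25 and 1.22 higher (adjusted p = 0.16 and 0.12), and Serpina3n stood at 164 ± 8.5 CPM in sham and 223 ± 19.98 CPM in I/R (adjusted p = 0.078).

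Il4ra, the receptor chain shared by interleukin 4 and interleukin 13, stood at 60.3 ± 8.32 CPM in sham and 67.6 ± 2.84 CPM in I/R (log2 fold change 0.17 ± 0.11, adjusted p = 0.67). Of 5 measured members of that axis none was called by edgeR, DESeq2 or limma-voom with the filter on low counts (camera adjusted p = 0.14). Il13ra1 was the 1 member with an unadjusted p under 0.05, and it was higher when adjusted over the list alone (0.64 ± 0.15). Without the filter, edgeR called Il13ra1 over all genes (adjusted p = 0.029). Of 20 interferon response genes none was called over all genes by edgeR, DESeq2 or limma-voom, or over the list alone in edgeR's test, and 6 had an unadjusted p under 0.05 (camera adjusted p = 0.18), with Ifi44 at 0.95 and Ifit1 at 0.49, and the list was called higher without I/R 2 (adjusted p = 0.024). Of 10 neutrophil and monocyte genes none was called by those 3 tools and 1 had an unadjusted p under 0.05, Camp at -0.84 (list median -0.17, camera adjusted p = 0.21). Among 3 measured lymphocyte genes, Ighm, the heavy chain of immunoglobulin M, fell by 0.73 ± 0.13 over all genes and over the list alone (camera adjusted p = 0.64), and lost its call without sham 1, sham 2, I/R 1 or I/R 2 (adjusted p 0.0755 to 0.133).

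Hormone and stress programs moved by small amounts. The glucocorticoid response list rose (median 0.39, camera adjusted p = 2.4e-05), with adjusted p = 0.31 with an estimated correlation. Cdkn1a, a cell cycle inhibitor, rose by 0.64 ± 0.10 as 1 of 15 members over all genes, 6 rose when adjusted over the list alone, and the steroid-induced genes Klf9 and Zbtb16 stood 0.46 and 0.69 higher (adjusted p = 0.071 and 0.099), with adjusted p = 0.039 for Klf9 without sham 3. The heat shock list fell (median -0.18, camera adjusted p = 0.014), with adjusted p = 0.27 with an estimated correlation, 0.0743 without I/R 3 and 0.0617 against sham 2 alone. Hsph1, a chaperone, fell from 306 ± 16 to 209 ± 8.13 CPM as 1 of 11 members over all genes and 3 fell when adjusted over the list alone, while Hspa1b had a log2 fold change of -0.82 (adjusted p = 0.092). Cdkn1a lost its call without sham 1 or I/R 2 (adjusted p 0.0939 and 0.0909), and Hsph1 without sham 1, sham 2, I/R 2 or I/R 3 (0.0564 to 0.0802).

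Of 16 clock genes, Dbp, an output transcription factor, fell by 0.97 ± 0.16 and Nfil3, its repressor counterpart, rose by 0.69 ± 0.14, while Nr1d1 had a log2 fold change of -0.79 (adjusted p = 0.099). The list was not called (camera adjusted p = 0.73), with 1 higher and 4 lower when adjusted over the list alone. Dbp lost its call without sham 1, sham 3 or I/R 2 (adjusted p 0.0656 to 0.109) and Nfil3 whichever of the 6 libraries was left out (0.0621 to 0.240). The hypoxia, stress response, cholesterol and proliferation lists were not called and had no member called over all genes in edgeR's main fit. Of 13 hypoxia genes, 3 had an unadjusted p under 0.05, 1 was called by DESeq2, and 2 were higher and 1 lower over the list alone (camera adjusted p = 0.79). The glucose transporter gene Slc2a1 stood at 0.49, and edgeR called it with robust dispersion (adjusted p = 0.044) and without the filter on low counts (0.0095). Of 15 unfolded protein and integrated stress response genes, 4 had an unadjusted p under 0.05 and 1 was higher over the list alone, Chac1 at 0.56 (camera adjusted p = 0.41). Of 15 cholesterol synthesis genes 1 had an unadjusted p under 0.05, Msmo1 at -0.32 (camera adjusted p = 0.064), and of 10 proliferation genes 2 did, Kif11 at 0.68 and Rrm2 at -0.78 (camera adjusted p = 0.38). Neither DESeq2 nor limma-voom called a member of these last 3 lists. The cholesterol list was called lower without I/R 3 (adjusted p = 0.045), with a CPM of at least 1 in 3 libraries (0.047), with the replicate block (0.039) and by fry (0.027), and the proliferation list higher by fry (0.023).

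Nuclear genes of oxidative phosphorylation were lower as a group (median log2 fold change -0.24 over 27 genes, camera adjusted p = 0.0085), with adjusted p = 0.79 with an estimated correlation and 0.63 by fry. None of the 27 was called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05. Their summed level followed single libraries, at 2195, 1986 and 3184 CPM in sham 1 to 3 and 3023, 1933 and 1416 CPM in I/R 1 to 3, and Ndufs6 and Cox7a2 overlapped between the groups. The list had adjusted p = 0.647 without sham 3, 0.0732 without I/R 2, 0.904 without I/R 3 and 0.614 with the muscle covariate, and it turned upward against sham 2 alone (0.951). The ribosomal protein list, a quality list of 25 genes, moved with the same libraries, at 3044, 2889 and 3983 CPM in sham and 4028, 2895 and 2337 CPM in I/R, and was not called (camera adjusted p = 0.15), with Rps27 at -0.28, but was called lower without sham 2 (adjusted p = 0.0185) or I/R 1 (3.3e-06), and turned upward without a call without sham 3 or I/R 3. Mitochondrially encoded genes were not called (camera adjusted p = 0.73), with 8 of 13 above 0, a median of 0.06, mt-Atp6 at -0.39 and mt-Co3 at 0.97. The value for mt-Co3 ran from 0.17 without I/R 2 to 1.67 without sham 1, and the gene passed without the filter on low counts (adjusted p = 0.045). The sex-linked list was not called (camera adjusted p = 0.21) but was called higher without sham 3 (adjusted p = 0.042), and Ddx3y, a Y-linked gene, had 442 to 654 counts in each library. With the filter, no member of these 3 quality lists was called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05.

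Glial and vascular lists were not called by camera with all 6 libraries, while fry called satellite glia lower (adjusted p = 0.030) and camera called the myelinating Schwann cell list lower without I/R 2 (adjusted p = 0.042). Among 12 satellite glia genes, Fabp7, a fatty acid binding protein of glia, fell from 154 ± 36.5 to 77.5 ± 9.91 CPM, with 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.15). Fabp7 lost its call without sham 1, I/R 2 or I/R 3 (adjusted p 0.0680 to 0.127). Of 14 myelinating Schwann cell genes none was called by edgeR, DESeq2 or limma-voom over all genes, 4 had an unadjusted p under 0.05 and 3 fell over the list alone (camera adjusted p = 0.14), with Mag, a myelin-associated glycoprotein gene, at -0.41. The repair Schwann cell (7 genes, camera adjusted p = 0.93), endothelial (12 genes, 0.57) and mural and smooth muscle lists (9 genes, 0.23) likewise had no called member in these 3 tools, with 1, 2 and 1 members at an unadjusted p under 0.05, and examples were Runx2 at 0.38, Vwf at 0.39 and Des at -1.42, which stood highest in sham 1 at 15.03 CPM and was called without sham 2 (-1.77, adjusted p = 0.015), but had a log2 fold change of -0.77 without sham 1.

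The adipocyte, bone and cartilage, and spinal cord lists were not called by camera with all 6 libraries. Of 4 measured adipocyte genes, Plin4, a lipid droplet protein, rose by 1.86 ± 0.26 and Fabp4 fell by 1.56 ± 0.30, with 1 higher and 2 lower over the list alone (camera adjusted p = 0.73). Of 7 bone and cartilage genes, Col2a1, the cartilage collagen gene, fell by 1.56 ± 0.26 over all genes and over the list alone (camera adjusted p = 0.27). Of 6 spinal cord genes none was called by edgeR, DESeq2 or limma-voom over all genes and 3 had an unadjusted p under 0.05, with 1 lower over the list alone (camera adjusted p = 0.27). Without sham 2 the spinal cord list was called lower on 8 genes (adjusted p = 5.84e-06). Fabp4 lost its call whichever of the 6 libraries was left out (adjusted p 0.0693 to 0.165), and Col2a1 without sham 1, sham 2, sham 3 or I/R 2 (0.0579 to 0.0693). Adjustment over the list alone used edgeR's test, and where no such count is given for a list, it was 0.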

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

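All 188 called genes that an alternative tested kept their direction there (176 tested with a CPM of at least 1 in 3 libraries). All 188 had I/R values outside the range of their sham values. Leaving out libraries could therefore hardly reverse them, and the kept direction adds little. Calls passed in all 16 alternatives for 12 of the 24 top genes. Of 2291 values of 144 named genes, 1994 stayed on their side of the threshold, 39 passed it, 258 no longer did and none that was called changed direction. DESeq2 called 312 genes, 143 of them lower, and the fit without a filter, on 29449 genes, called 494, with 257 higher, 237 lower and 276 changed 2-fold; the cause was not tested. Leaving out 1 library gave 87 to 181 calls, 62 to 116 higher, 24 to 85 lower and 72 to 146 changed 2-fold, on fewer samples. Of the alternatives added after seeing the data, the muscle covariate gave 28 calls (20 higher, 8 lower, 28 changed 2-fold) and sham 2 alone against I/R 32 (25 higher, 7 lower, 32 changed 2-fold), both with fewer degrees of freedom. Replicate numbers did not pair the libraries, since deviations of same-numbered libraries correlated at -0.106, 0.135 and -0.123 and not every library correlated best with its own number. The replicate block gave 63 calls (42 higher, 21 lower, 53 changed 2-fold). Camera called 11 lists, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05 and fry called 10, losing 4 of the 11 and gaining satellite glia, cholesterol synthesis and proliferation. At this depth and n, a change under 2-fold is often missed.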

Other observations

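Enrichment, the sham 2 and muscle covariate fits, and the tests on the clamp, on blood makeup and on globin paralogs were chosen only after the results were seen. Among the genes called higher, 11 Gene Ontology terms passed, led by positive regulation of reactive oxygen species metabolism (4 of 14 genes against 0.108 expected, adjusted p = 0.0059 in a one-sided hypergeometric test). Without predicted and unnamed genes 2 of these terms passed, that one (adjusted p = 0.0065) and inflammatory response (0.019), while 5 of 5 terms passed among the genes called lower. Inflammatory response held 8 of its 148 genes against 1.14 expected (adjusted p = 0.017), among them the complement gene C3, the metalloprotease gene Adam8 and Csf1. Csf1, and Crh and Gal, which are also among the 8, are on the nerve injury list, so the term is not independent of that list. C3 rose from 4.80 ± 0.649 to 16.8 ± 5.004 CPM and Adam8 from 11.1 ± 1.28 to 25.6 ± 1.13 CPM. Both kept their calls without each library in turn. With the muscle covariate both lost them (edgeR's adjusted p = 0.0677 for C3 and 0.148 for Adam8), and C3 also with the replicate block (0.0762). Among the genes called lower, 5 terms passed, led by collagen fibril organization with 6 of 39 genes against 0.187 expected (adjusted p = 4.4e-05). The same term also passed among genes called higher, with 4 of its 39 genes (adjusted p = 0.046), but not without the predicted genes (0.289), since 1 of the 4 was Gm21451, with 0 counts in sham and 55 in I/R. Lox and Loxl2, enzymes that cross-link collagen, rose by 1.05 ± 0.12 and 0.82 ± 0.14. Loxl2 lost its call without sham 1, sham 3, I/R 2 or I/R 3 (adjusted p 0.0725 to 0.137).

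Rbp4, a retinol binding protein, fell by 1.75 ± 0.35, and lost its call whichever of the 6 libraries was left out (adjusted p 0.0628 to 0.217). Some calls rested on few counts. Lipn, a lipase gene, had 0 counts in sham and 49 in I/R, and lost its call without sham 1, sham 3, I/R 2 or I/R 3 (adjusted p 0.0567 to 0.1055). Tnfrsf8, a receptor gene, had 1 and 85, a ratio of 81.0 with a counting interval of 14.1 to 3234, and 0 sham counts are left without sham 2. The predicted genes Gm5152 (0 and 132 counts), Gm3883 (66 and 0) and Gm21451 have unknown overlap with related sequences, so their counts are uncertain, and Gm21451 lost its call without sham 1, I/R 2 or I/R 3 (adjusted p 0.0517 to 0.0941).

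The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 188 calls and the highest other split 2, 113 calls of at least 2-fold against 1, and 11 lists against 9. For each of these results, 1 split, the real one, gave as much. Lists called in the other splits numbered 0, 5, 9, 6, 9, 6, 5, 5 and 6, however, so the list count barely sets the real split apart.

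The rise of the nerve injury list is the clearest pattern. A larger share of neurons in I/R needs pan-neuronal genes to rise as well, and 15 of them had a median log2 fold change of 0.0324 (95% interval -0.05 to 0.07). Muscle in 2 sham libraries needs the rise to shrink under 0.5 against sham 2 alone, where the median was 1.57 (0.93 to 3.41). The interval reaches under the bound of 1 set to speak against it and rests on 1 sham library. With the muscle level as a covariate, on all 6 libraries, the list was still called higher (camera adjusted p = 1.1e-33 at the fixed correlation). These values argue against muscle as the whole of the rise, and muscle stays open as a part of it. Mechanical damage of renal nerve fibers by the clamp cannot be told apart from ischemia, because 0 sham libraries had a clamp, nor from removal of the right kidney if sham mice kept theirs, and a response of renal sensory neurons to kidney ischemia stays a hypothesis of the same standing.

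The fall of the fibroblast and meningeal list may come from less meningeal tissue taken with the I/R ganglia. A separate list of 16 meningeal markers had a median log2 fold change of -0.84 (95% interval -1.27 to -0.24), with all 16 below 0 and 4 called lower, Slc22a6, Slc13a4, Slc47a1 and Aldh1a2 (camera p = 4.9e-11, and p = 0.0036 with an estimated correlation). Each of the 4 lost its call in 4 to 6 of the 6 fits without 1 library, namely Slc22a6 in all (adjusted p 0.0544 to 0.101), Slc47a1 in all but that without sham 1 (0.111 to 0.182), Aldh1a2 in all but that without I/R 1 (0.0599 to 0.0909) and Slc13a4 without sham 1, sham 2, I/R 2 or I/R 3 (0.0551 to 0.105). That interval reaches above the -0.3 set to speak against this explanation, and ganglia also express members such as Cdh1 (271 CPM in sham), so it stays open. Connective tissue attached to the muscle needs the fall to vanish against sham 2 alone, where the median was -1.003 (-1.48 to -0.62), on 1 sham library. A fall there was all but fixed in advance, because 8 of the 12 members were called and had each I/R value below each sham value. Only its size was free, and the fall was no smaller than with all 6 libraries (median -0.94). Lower collagen synthesis was not decided by 14 collagen-processing enzymes, whose median of -0.0511 (-0.21 to 0.07) reaches past the bound of -0.1 set to speak against it, with Pcolce at -0.90, and a response of meningeal cells to I/R was not tested.

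The fall of the erythroid list is not explained by reads moving between globin copies, since the summed 4 genes differed by -1.68 on the log2 scale (-2.37 to -1.07 over pairs of libraries). Less blood of the same makeup needs white cell genes to fall alike, and the neutrophil and monocyte list had a median of -0.17 (95% interval -0.32 to 0.02). Of its 10 measured genes 7 lay below 0, with Camp at -0.84 and S100a8 at -0.37, and 3 above. Of 3 lymphocyte genes, Ighm fell by 0.73 and 2 lay above 0. Because 10 of its 16 genes were measured and Camp stood at 1.26 CPM in sham, the list cannot exclude less blood as a part of the fall. Fewer red cells in the blood or a different clearing of blood from the tissue might account for the fall, and neither was tested.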
